A study of Escherichia coli K-12 with 26 samples.

How the data were processed

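Strand-specific total RNA sequencing libraries of *E. coli* K-12 were made by the submitters with an adapted SOLiD total RNA kit. Per the labels' protocols, DNase-treated RNA was fragmented with RNase III, some samples were digested with Terminator exonuclease, pyrophosphate was removed from 5′ ends with tobacco acid pyrophosphatase, and adapters were joined to those ends. Per the submitters' processing notes, Bowtie 1.8 and SAMtools were used, with no role stated. The genome build, the method that called promoters and terminators, its thresholds, and which libraries were pooled are not given in the sources used here. The libraries were grouped by strain, growth stage and RNA treatment as the labels give them. These groups describe the study and entered no test.

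The 1 processed file used here is an annotation deposited by the authors in the form of a feature table. It lists genome positions of operons, promoters and terminators with the authors' class or gene names, and holds no read counts, expression values or columns for single libraries. The depth per library is therefore unknown. The planned comparisons of stationary with logarithmic phase and of *rpoS* mutant with wild type, in both growth stages, were not run. The planned search for a growth phase class among promoters was not run because the table gives no such class. Leader lengths, promoter sequence elements and genes assigned by position were not analysed here, since they need a genome or gene positions of the same build.

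Each promoter and terminator was assigned to the operon under which it is listed. Every promoter and terminator lay within its operon and on its strand. A terminator was called inner when its position differed from the operon's 3′ end. The authors' class was not used for this, because all 750 forward-strand 3′ ends carry the class terminal while all 760 reverse-strand 3′ ends carry the class internal. Promoter classes were used as given. An operon was called complex when it held a promoter of class internal away from its 5′ end or an inner terminator. The plan named a promoter inside the operon without a class, so this definition is narrower than the plan. Gene names were matched to the reference gene table of assembly ASM584v2, which was used for names and gene order only. Of 2947 names, 2714 matched a symbol and 229 an older name, and 4 (*ptwF*, *adrB*, *rdoA* and *yjeP*) matched none. The genes of 583 of 628 multi-gene operons with all names matched (92.8%) were consecutive in the reference. A gene that is not named in any operon is called not named here, whatever its transcription.

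Shares were given exact Clopper-Pearson intervals, the mean number of genes an interval of 2 standard errors over operons, strand shares an exact binomial test against 50%, and differences of shares Fisher's exact test. Median overlaps were compared by a permutation test with 100000 resamples. Gene lists were tested with Benjamini-Hochberg adjustment over the lists, with permutations within classes of equal gene number for complex operons, and with all 4651 rotations of the gene order for named genes. The tests of how many genes of a list were named, of convergent against divergent overlaps and their medians, of complex operons by size, and the size-matched and rotation tests were chosen after the data were seen. All tests were two-sided, with a threshold of 0.05. Neighbouring operon pairs were taken among operons with gene names after leaving out operons nested in another. On a circle the numbers of convergent and divergent pairs are equal by construction. Overlaps counted from 1 nt.

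The named genes followed a rule fixed before the data were examined. It takes the 5 operons with most genes, with most promoters and with most terminators, the 5 longest convergent and the 5 longest divergent overlaps, the 5 longest antisense and the 5 longest unannotated transcripts, with ties in genome order. It also takes the textbook operons, *rpoS*, and from each gene list the 3 genes with the largest and the 1 with the smallest value of the quantity described. The rule did not name that quantity, which was taken here as the number of genes in the operon. The 5 longest leaders of the rule were not analysed here. Its unannotated transcripts were taken as operons without gene names, which were not compared with gene positions. Other genes were named after their values were seen, where a count was 5 or fewer or a feature was singled out. The gene lists were RpoS-dependent stationary phase genes, ribosomal proteins, flagella and chemotaxis, TCA cycle, ATP synthase and NADH dehydrogenase I, amino acid biosynthesis, heat shock, small regulatory and structural RNAs, attenuation leader peptides, and genes with known long regulated leaders.

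The procedures were tested on simulated data. In a simulated annotation of 1340 operons all gene numbers, all complex operons, and the arrangement and overlap of all 1339 neighbouring pairs were recovered. For simulated lists of 40 genes in neighbouring groups with no difference, Fisher's exact test called 36 of 200 and rotation called 5 of 200, so the rotation values are printed beside the Fisher values. With 30 percentage points added, rotation called 162 of 200. For lists of larger operons whose complex share was set by size alone, Fisher's exact test called 22 of 200 and the size-matched permutation 10 of 200. The test of medians called 8 of 200 without a difference and 197 of 200 with a shift of 100 nt. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.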

Results

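Total RNA of *Escherichia coli* K-12 was sequenced strand by strand on the SOLiD platform, from the wild type and from an isogenic mutant without *rpoS*, the gene of the stationary phase sigma factor RpoS. Cells grew in MOPS minimal medium with glucose as the only carbon source. The wild type is BW38028 in the substrain label and BW38038 in the growth protocol, and the mutant is BW39452. The 26 libraries fell into 22 groups, 17 libraries from the wild type and 9 from the mutant. RNA was used as extracted in 10 libraries, was depleted of ribosomal RNA in 12, and was depleted and treated with Terminator exonuclease, an enzyme that degrades RNA with a 5′ monophosphate, in 4. Wild-type cells were sampled from OD600 0.1 to 1.6 and at 15, 30 and 180 min after entry into stationary phase. Ribosomal RNA-depleted libraries at OD600 0.4 and at 30 min were made in 2 replicates for each strain, and the other 18 groups had 1 library each. The data analysed here are the transcriptome annotation the authors made from these libraries, which lists the positions of operons, promoters and terminators. Which of the libraries entered it is not given in the sources used here. It gives no value per library, so the depth is unknown and there are no replicates. For the same reason wild type and *rpoS* mutant, or logarithmic and stationary phase, were not compared here. Intervals are exact 95% Clopper-Pearson intervals that cover counting error only, since the features of 1 annotation are not replicates. The genome build behind the positions is not given in the sources used here.

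The first question was what was mapped on each strand. The annotation held 1510 operons, 2123 promoters and 1774 terminators, from position 114 at the *thr* operon to position 4639660. Of the operons, 750 (49.7%, interval 47.1 to 52.2%) lay on the forward strand and 760 on the reverse strand, which did not differ from an even split (exact two-sided binomial p = 0.817). Nor did promoters (49.1% forward, exact p = 0.435) or terminators (49.5% forward, exact p = 0.687). The authors classed 1412 promoters as primary, 416 as secondary, 208 as internal and 87 as antisense. Gene names were given for 1340 operons, which together named 2947 genes, and 170 operons had no gene name. Of the reference genes of assembly ASM584v2, 2943 of 4651 (63.3%) were named in an operon. Among them were all 22 ribosomal RNA genes, 79 of 86 transfer RNA genes, 2795 of 4290 protein-coding genes (65.2%), 27 of 145 pseudogenes (18.6%) and 19 of 107 noncoding RNA genes (17.8%).

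Most operons were small, while 20 held 10 or more genes. Operons with names held 2.20 ± 2.12 genes (mean ± SD over 1340 operons, median 1). A single gene was named in 710 of them (53.0%, interval 50.3 to 55.7%), yet the 630 operons with 2 or more genes held 2237 genes (75.9%). The largest had 28 genes, from *rpsJ* to *rplQ*, and joined on the reverse strand from 3437617 to 3451463 the S10, *spc* and alpha ribosomal protein clusters with *secY*, which encodes a subunit of the protein export channel, and *rpoA*, which encodes the alpha subunit of RNA polymerase. Next came a forward-strand operon of 19 genes from *mraZ* to *mutT* (89363 to 111873, 22511 nt), which holds the *mur* and *fts* genes of peptidoglycan synthesis and cell division. An operon of 18 genes ran from *tff* to *accA* (189641 to 209603), with *rpsB*, *tsf*, *bamA* and *dnaE* among them. The nitrate reductase and cytochrome *c* maturation genes *napF* to *ccmH* formed an operon of 15 genes (2289304 to 2301599), and *ybgC* to *lysQ*, with the *tol-pal* envelope genes and 7 transfer RNA genes, formed one of 14 (773935 to 781036).

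Textbook operons fixed before the data were examined were found whole in 23 of 29 cases (79.3%, interval 60.3 to 92.0%). The *atp* operon of ATP synthase (9 genes, 3913552 to 3920547) and the *nuo* operon of NADH dehydrogenase I (13 genes, 2387784 to 2403399) were annotated with exactly the listed genes, as were *sdh-suc*, *groS-groL*, *dnaK-dnaJ*, *hdeA-hdeB*, *gadB-gadC*, *otsB-otsA* and *pstS* to *phoU*. Leader peptide genes were added in front of *trp*, *his*, *thr* and *leu*. Other neighbours were joined to *gal* (*gpmA*), *cyo* (*yajR*), *cyd* (*ybgT* and *ybgE*) and *ptsH-ptsI-crr* (*cysK*). The *rpoB-rpoC* operon, which encodes the large subunits of RNA polymerase, was annotated with 13 genes from *thrU* onwards, *rpsL* to *tufA* lay in an operon of 9 genes that starts with *fkpA*, and *rpsO-pnp* lay in the operon of 10 genes from *rimP* to *deaD*. In the *lac* operon only *lacY* and *lacA* were named (360315 to 362424). No gene was named for the remaining 5 operons, arabinose *araB-araA-araD* and the flagellar and chemotaxis operons that begin with *fliF*, *flgB*, *motA* and *tar*. Whether the strain carries the *lac* and *ara* genes that were not named cannot be told from the annotation.

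**Figure D1:**
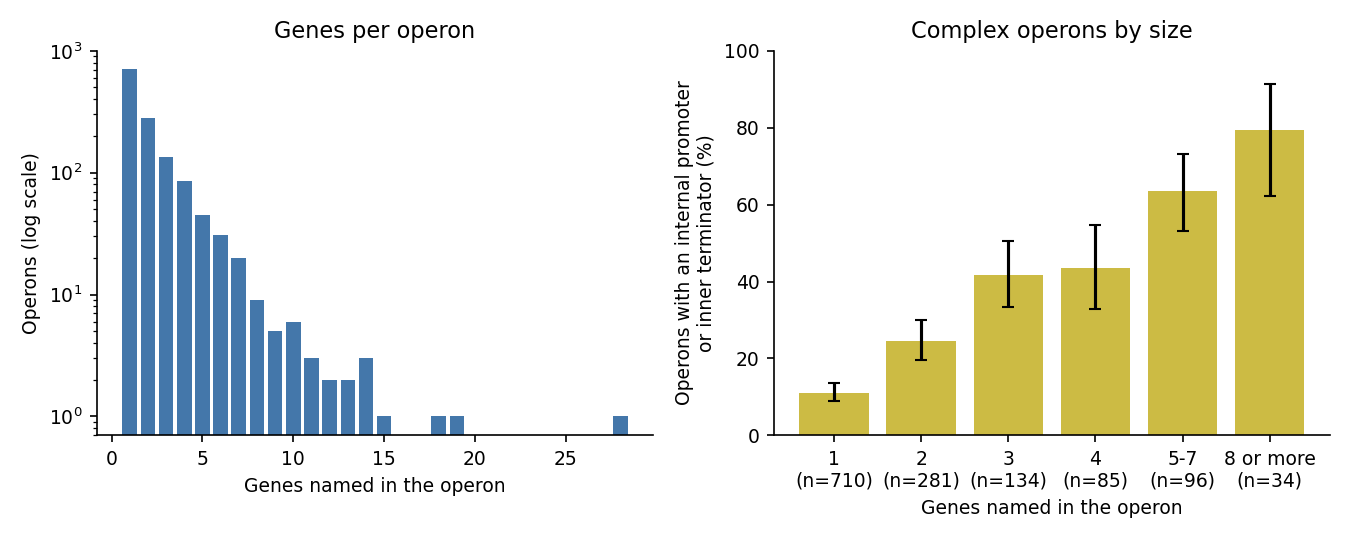
Left, number of operons (log scale) by the number of genes named in them, for the 1340 operons with gene names. Right, share of operons with an internal promoter or an inner terminator (%) by number of genes, with exact 95% intervals: it was 11.1% with 1 gene and 79.4% with 8 or more genes.

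How often an operon carried more than 1 transcription unit was asked next. Of the 630 operons with 2 or more genes, 250 (39.7%, interval 35.8 to 43.6%) had a promoter of class internal or a terminator ahead of their 3′ end. An internal promoter was present in 125 (19.8%), an inner terminator in 168 (26.7%) and both in 43 (6.83%). Larger operons were complex more often, 88 of 130 (67.7%) with 5 or more genes against 69 of 281 (24.6%) with 2 genes (Fisher exact p = 1.07e-16, two-sided, as are all tests, and chosen after the data were seen). A larger operon has more places for such features. No rate per gene or per length was computed, so the test does not show a higher rate in larger operons. A secondary promoter inside the operon, not counted so far, was present in 251 of the 630 operons (39.8%). Counting these promoters too, as the planned wording would, raised the share to 59.7%. Counting internal promoters alone lowered it to 19.8%. The operons *pdxB* to *ubiX* (2425981 to 2435910), with *accD*, *folC* and *purF*, and *yjeF* to *rlmB* (4391701 to 4408049), with *hfq*, which encodes an RNA chaperone, and *mutL*, had 8 promoters each. The *mraZ* operon and *ybaN* to *hemH* (490084 to 498459), which holds the heat shock gene *htpG*, had 7 each, and *tomB-hha-maa-ylaC* (477987 to 480104) had 6. Most terminators, 4 each, were mapped in the operons that start with *tff*, *ybaN*, *rimP* and *yjeF*, followed by *lptD* to *apaH* (50131 to 57252) with 3.

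The gene *rpoS* itself was the last of 12 genes in the operon *cysD-cysN-cysC-ygbE-ftsB-ispD-ispF-truD-surE-pcm-nlpD-rpoS*, on the reverse strand from 2864519 to 2874391 (9873 nt). It had 5 promoters. Its primary promoter lay at 2874391, ahead of the sulfate assimilation gene *cysD*. Internal promoters lay at 2871409, 2868640 and 2866139 and a secondary one at 2870922. The last internal promoter was 1620 nt from the 3′ end of the operon, and an inner terminator at 2865455 was 936 nt from it. Among the other genes with known long leaders, *hfq* lay in the operon of 14 genes from *yjeF*, *rpoE*, which encodes the envelope stress sigma factor, in one of 11 genes with 4 promoters, and *ribB* alone with 1 promoter.

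**Figure D2:**
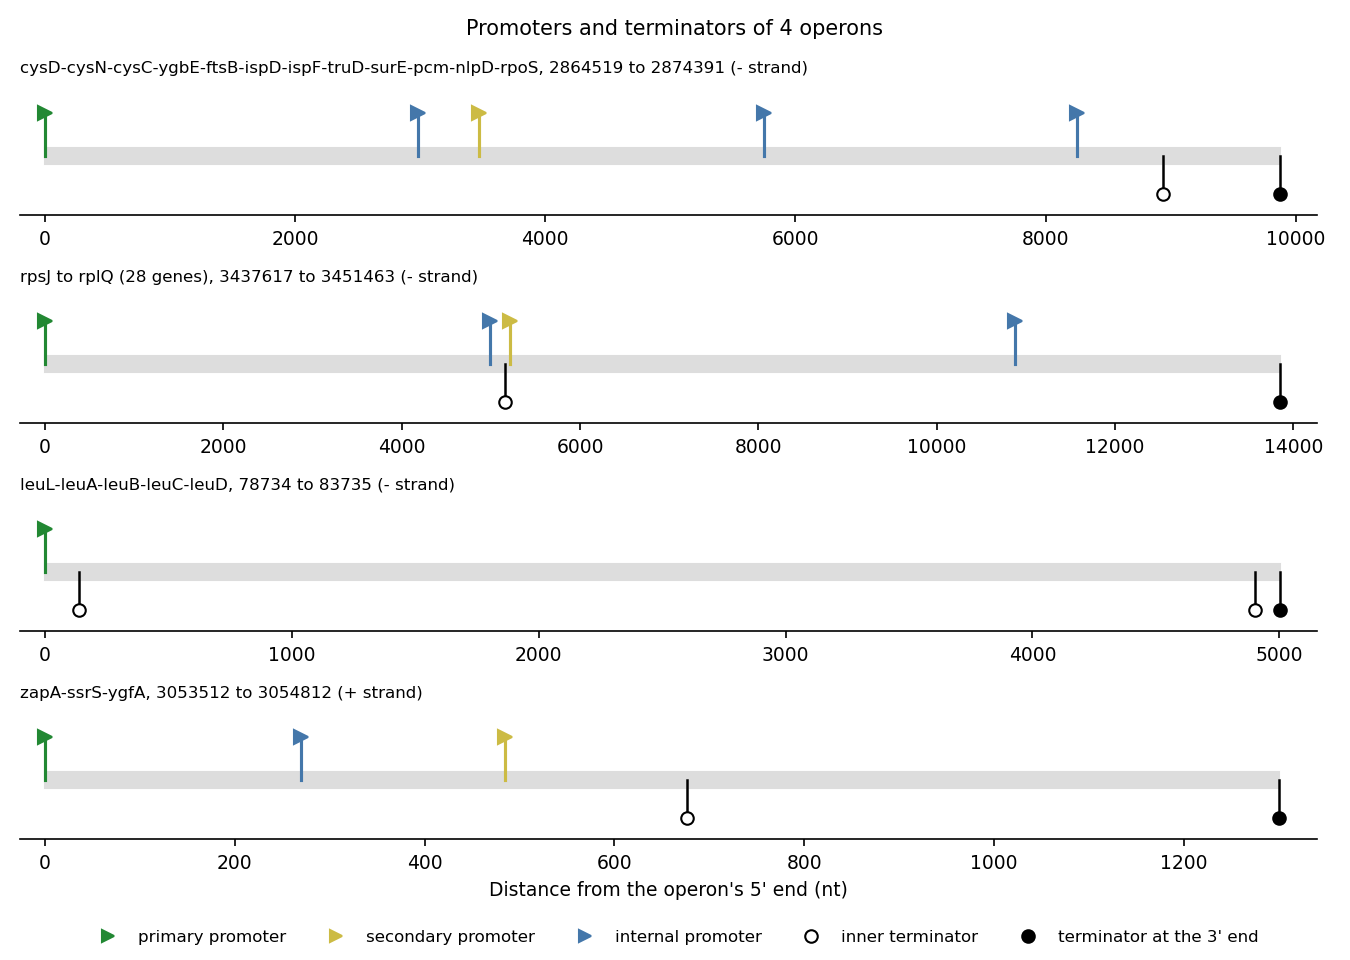
Promoters (flags, coloured by the authors' class) and terminators (circles, open inside the operon and filled at its 3′ end) of 4 operons, by distance from the 5′ end (nt, 1 scale per operon); grey bars are the operons. The *rpoS* operon had 5 promoters, and *leuL-leuA-leuB-leuC-leuD* had a terminator 138 nt after its promoter.

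The gene groups, whose members were fixed before the data were examined, differed in how many of their genes were named in an operon. All 37 genes of the RpoS-dependent stationary phase list were named, against 63.0% of the other reference genes. The same held for all 54 ribosomal protein genes, all 78 genes of amino acid biosynthesis, all 22 of ATP synthase and NADH dehydrogenase I, all 16 heat shock genes, all 11 attenuation leader peptides and all 16 genes with known long leaders. Of the 16 TCA cycle genes 15 were named, all but *fumB*, which encodes an anaerobic fumarase. Only 2 of 51 flagellar and chemotaxis genes (3.92%, interval 0.478 to 13.5%) were named, *flhD* and *flhC*, which encode the master regulator of the flagellar genes. Each of the 10 lists differed from the other genes by Fisher's exact test (Benjamini-Hochberg adjusted over the 10 lists, p from 1.65e-18 for flagella to 0.0209 for small RNAs). This comparison was chosen after the data were seen. So was a narrower background, protein-coding genes with locus tag numbers up to 4500, of which 66.8% outside the RpoS-dependent list were named. Against it, every list other than small RNAs kept its direction (adjusted Fisher exact p of 0.0291 or less). The test takes neighbouring genes as independent. With the gene order rotated, which keeps neighbours together, adjusted p was 0.00108 for RpoS-dependent, ribosomal, flagellar and amino acid genes, 0.0043 for long leaders, 0.0118 for leader peptides, 0.0141 for heat shock and 0.0293 for small RNAs. The TCA cycle (adjusted p = 0.121) and ATP synthase with NADH dehydrogenase I (adjusted p = 0.065) did not pass this exact rotation test.

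Within the RpoS-dependent list, *xthA*, which encodes exonuclease III, lay in an operon of 8 genes with *ydjX* to *ynjD*. The *elaB* gene lay in an operon of 8 with the *men* genes of menaquinone synthesis, and *narZ*, of nitrate reductase Z, in one of 5. The morphogene *bolA* stood alone with 2 promoters. Among ribosomal protein genes *rplQ*, *rpsD* and *rpsK* lay in the operon of 28 genes and *rpsT* stood alone. TCA cycle genes *sdhC*, *sdhD* and *sdhA* shared 1 operon of 8 genes, and *acnB*, an aconitase gene, stood alone. *nuoN*, *nuoM* and *nuoL* lay in the operon of 13 genes, *atpC* in that of 9. For amino acid biosynthesis *hisG*, *hisD* and *hisC* lay in an operon of 9 genes that starts with *hisL*, and *dapB* stood alone with 2 promoters. Heat shock genes *htpG*, *ftsH* and *hslU* lay in operons of 8, 7 and 6 genes, *grpE* alone. The leader peptide genes *hisL*, *pheM* and *ilvL* lay in operons of 9, 8 and 7 genes, *mgtL* in one of 2 with *mgtA*.

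**Figure D3:**
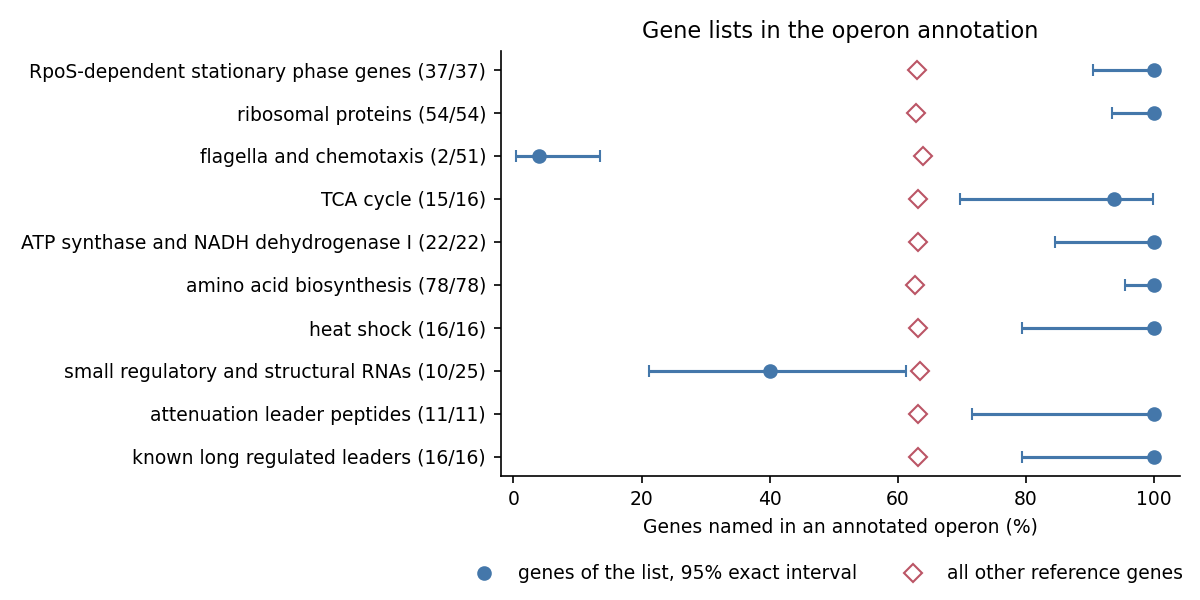
Share of each gene list named in an annotated operon (%, circles, with exact 95% intervals for counting error) beside the share among all other reference genes (diamonds); counts stand in brackets. Flagella and chemotaxis had 2 of 51 genes named.

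Of the small regulatory and structural RNAs 10 of 25 (40.0%, interval 21.1 to 61.3%) were named, fewer than the 63.4% of other genes. The 170 operons without gene names were not compared with gene positions. Some of the 15 RNAs that were not named may therefore have been mapped without a name. Set against the other noncoding RNA genes alone, of which 10 of 83 were named, the list was named more often (adjusted Fisher p = 0.00411). The direction for this list therefore depends on the background. No rotation value was computed for the noncoding background. CsrB, an RNA that binds the carbon storage regulator, was the gene with the most neighbours, in *syd-csrB-yqcC-truC-yqcA*, where a secondary promoter lay 352 nt ahead of the next terminator. 6S RNA (*ssrS*) lay in *zapA-ssrS-ygfA*, 191 nt from its nearest promoter to the next terminator. The *cyaR* gene lay in *yegP-yegQ-cyaR* with 142 nt between them. The *ffs* gene, of the signal recognition particle RNA, stood alone with 143 nt.

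Complex operons were also compared between gene lists, for the 7 of 10 lists with at least 3 operons of 2 or more genes. Secondary promoters were not counted in this comparison. By Fisher's exact test amino acid biosynthesis operons (23 of 34 complex, 67.6% against 38.1% of other operons, adjusted p = 0.00653) and ribosomal protein operons (11 of 15, 73.3%, adjusted p = 0.0461) stood above the others. Neither passed when operons were matched by their number of genes (permutation test, adjusted p = 0.251 and 0.555), which left 51.3% and 59.1% to be expected. Before adjustment the size-matched permutation p for amino acid biosynthesis was 0.0359, so an excess beyond size is not excluded there. RpoS-dependent operons (8 of 18, 44.4%) did not pass the test against the 39.5% of other operons (adjusted Fisher exact p = 0.808). Heat shock (6 of 9), small RNA (3 of 6), leader peptide (8 of 11) and long leader operons (8 of 14) did not pass either test.

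Neighbouring operons on opposite strands often overlapped, more so at their 3′ ends than at their 5′ ends. Of 442 convergent pairs 236 overlapped (53.4%, interval 48.6 to 58.1%), by a median of 267 nt (mean 281 ± 176 SD). Of 442 divergent pairs 122 overlapped (27.6%, interval 23.5 to 32.0%), by a median of 111.5 nt (mean 159 ± 173 SD). The shares differed by 25.8 percentage points (Fisher exact p = 6.52e-15), in a test chosen, like that of the medians, after the data were seen. Among pairs whose facing genes are direct neighbours in the reference gene order, 213 of 280 convergent (76.1%) and 115 of 330 divergent pairs (34.8%) overlapped, a difference of 41.2 percentage points. The median overlaps differed by 155.5 nt (permutation test, p = 1e-05, the smallest that 100000 resamples can give). Neighbours on the same strand overlapped in 5 of 441 pairs.

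The longest convergent overlap, 1396 nt (3794870 to 3796265), joined *rfaD-rfaF-rfaC-rfaL* to *rfaQ* to *waaU*, both of lipopolysaccharide core synthesis. The lipoprotein gene *nlpA* overlapped *yicL* by 860 nt, *fbp*, a fructose bisphosphatase gene, overlapped *ytfQ-ytfR-ytfT-yjfF* by 708 nt, *trmA* overlapped *fabR-yijD* by 701 nt and *gapC* overlapped *aldA* by 695 nt. The longest divergent overlaps were 893 nt between *yoaH* and *pabB-nudL-sdaA*, 790 nt between *tesA-ybbO-ybbN* and *ybbA-ybbP*, and 787 nt between *zwf*, of glucose 6-phosphate dehydrogenase, and *yebK-pykA*. They were followed by 772 nt between *sbcD-sbcC-araJ* and the phosphate regulators *phoB-phoR*, and 507 nt between *yfbV-yfbU-yfbT* and the acetate genes *ackA-pta*. A further 15 named operons lay wholly inside an operon of the other strand and were left out of the pairs.

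**Figure D4:**
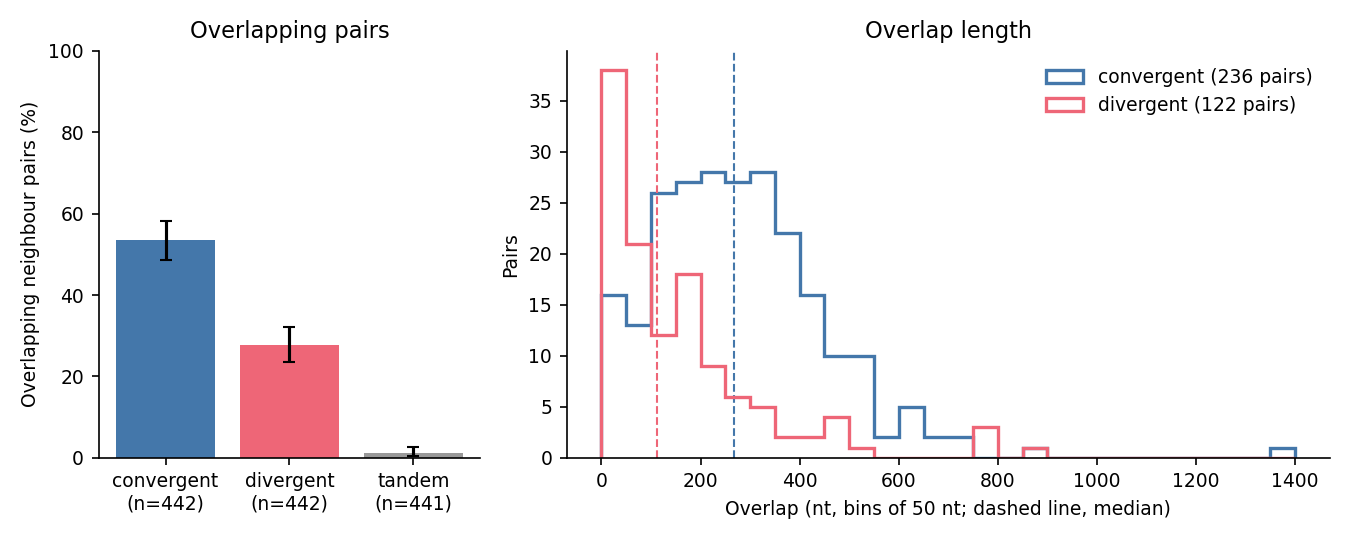
Left, share of neighbouring operon pairs that overlap (%), by arrangement, with exact 95% intervals. Right, number of overlapping pairs by length of overlap (nt, bins of 50 nt), with the medians of 267 nt for convergent and 111.5 nt for divergent pairs as dashed lines.

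The 170 operons without gene names were short, with a median of 377 nt against 1589 nt for operons with names. An antisense promoter began 83 of them (410 ± 227 nt, mean ± SD). Of these, 34 lay inside a named operon of the other strand, 19 overlapped part of one and 30 overlapped none. The longest, 1169 nt from 1754250 to 1755418, overlapped *pykF*, which encodes pyruvate kinase I, by 928 nt, and *lpp*, which encodes the major outer membrane lipoprotein, by 11 nt. The next had 1034 nt, of which 1017 nt lay against *lacY-lacA*, 934 nt inside *parC-plsC-ftsP-ygiQ*, 892 nt at 3287036 to 3287927 against no named operon, and 879 nt, of which 747 nt lay against *hiuH-yedY-yedZ*. Among all operons without names the longest had 3464 nt (2776159 to 2779622, reverse strand), and those of 2858, 2562, 2072 and 2028 nt followed. The last of these overlapped *hchA* by 11 nt, and that of 2072 nt overlapped *ravA* by 26 nt. Operons without names were not compared with gene positions, so they may hold known genes.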

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

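Several alternatives were chosen only after the data were seen. They were the change of background, the rotation of the gene order, and the RpoS-dependent list without *gad* and *hde* genes. Others were the use of all operons or of pairs of directly neighbouring genes, another terminus, and other limits for early terminators. So was the 50 nt minimum for the difference between convergent and divergent shares. The plan named a promoter inside the operon without a class, so counting secondary promoters is closer to it than the reported share. Of 42 alternative values, 3 say nothing, because no feature shared a position and leaving such features out changed no strand share. Of the other 39, 33 kept their direction and their side of the threshold or, for values without a test, stayed within their 95% interval or, for counts, within 1.5 times the reported count. The mean of 2.20 genes per operon (95% interval 2.08 to 2.31) became 2.15 with protein-coding genes only and moved to 1.95 with operons without names counted as 0 genes, by construction. The share of complex operons moved to 19.8% with internal promoters only and to 59.7% with secondary promoters counted, by construction of what is counted. The list of small RNAs turned from a difference of -23.4 percentage points from other genes to one of 28.0 when set against other noncoding RNA genes, few of which were named. The difference lost its threshold for the TCA cycle and for ATP synthase with NADH dehydrogenase I when the gene order was rotated. Counts of overlapping pairs stayed within that factor, but shares left their intervals: divergent overlaps fell to 84 of 442 pairs (19.0%) at 50 nt or more, and among directly neighbouring genes 76.1% of convergent and 34.8% of divergent pairs overlapped. The convergent minus divergent difference, 25.8 percentage points as reported, was 30.8 at 50 nt, 41.2 among direct neighbours and 47.8 with both. No paired analysis was possible because the annotation has no values per library. The alternatives planned for strain and growth stage comparisons, leader lengths, promoter elements, genes assigned by position, and operon ends nearest to a gene were not run, since they need values per library, a genome or gene positions of the same build. The depth is unknown, so a gene not named in an operon is not shown to be silent.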

Other observations

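All tests in this part were chosen after the results they bear on were seen, and genes outside the rule for named genes were chosen after their values were seen. The 7 ribosomal RNA operons each had a secondary promoter 109 to 119 nt after the first (median 115 nt), against a median of 410 nt in 328 other named operons. Of the 15 named operons inside an operon of the other strand, *gadY*, an RNA encoded opposite the acid resistance regulator gene *gadX*, lay within *gadX-gadW* (3662800 to 3662992). The others included *cspD* inside *macA-macB-clpS-clpA*, *bamD* inside *rluD-yfiH-ryfD-clpB*, *tpx* inside *ycjX-ycjF-tyrR-ycjG* and *can* inside *hpt-yadG-yadH-yadI*. The small RNA genes *spf*, *rybB* and *ssrA* were annotated at the end of operons with the genes ahead of them, *polA*, *ybjL* and *smpB*. Each also had a secondary promoter, 234, 91 and 437 nt ahead of the next terminator.

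Genes not named in an operon lay in long runs. The longest had 33 genes, from *intR* to *ynaM* in the Rac prophage, and others of 20 genes held hydrogenase 1 (*hyaA* to *cspH*) and colanic acid synthesis (*wcaM* to *wza*). Runs of 15 and 14 genes held flagellar genes (*flgN* to *flgO*) and the enterobactin genes *fes* to *entH*. Runs of 10 or more genes numbered 40 and held 572 genes.

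Terminator classes split by strand. All 760 operon 3′ ends of the reverse strand had the class internal and 0 had the class terminal, while on the forward strand all 750 were terminal. By position, inner terminators lay in 14.7% of forward and 16.1% of reverse operons, a difference of 1.39 percentage points (Newcombe 95% interval -2.26 to 5.03), which argues against a difference in termination as large as the split in classes. A class assigned without regard to the orientation of the reverse strand remains a candidate explanation, which the 760 ends that raised it do not test.

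Convergent operons overlapped more often than divergent ones. If the numbers of genes left unnamed between the pairs were the cause, the difference should vanish among direct neighbours, but it was 41.2 percentage points there. If longer operons were the cause, no excess should remain at matched operon length, but 56.0 more convergent pairs overlapped than the 180 expected (permutation p = 1e-05, the smallest that the permutations can give). How the authors placed transcript ends was not tested and remains open, and so does readthrough past the last gene as a hypothesis. Distances between the facing genes need gene positions of the same build, so neither comparison covers them.

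For the runs of genes not named, single genes missed at random are argued against. There were 530 runs, while 10000 shuffles of 1384 operon blocks gave 715 to 821. The blocks outnumber the 1340 named operons, so some operons were shuffled in pieces. Of the 572 genes in runs of 10 or more, 3.32% were named as insertion sequence genes. This argues against unplaced reads of insertion sequences for most of these genes. Other repeated sequences were not counted, so unplaced reads of those stay open. Deletion of the whole region from the strain is argued against for 13 of the 40 runs, where an operon without gene names was mapped between the flanking operons. A smaller deletion that leaves such an operon is not excluded. In the run *yecV* to *motR* the operon without gene names lay on the reverse strand from 1959916 to 1960389. Its 3′ end was close to the end of *argS* at 1959861. For the other 27 a deletion cannot be told apart from genes that were not transcribed or not detected in glucose medium, because the annotation holds no reads. Whole operons missed at random, and the growth medium, which all libraries share, were not tested and stay open.

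A first hypothesis was that early terminators mark attenuation. A terminator within 300 nt of a promoter was mapped in 4 of 11 leader peptide operons and in 30 of 1329 others (2.26%), a difference of 34.1 percentage points (Fisher exact p = 0.000101). The distances were 154 nt for *hisL*, 138 nt for *leuL*, 98 nt for *pheL* and 99 nt for *pheM*, the last 2 counted from secondary promoters inside their operons. From the promoter at the 5′ end alone, 2 of 11 leader peptide operons and 11 of 1329 others had an early terminator, a smaller difference of 17.4 percentage points (Fisher exact p = 0.00455). The operons of the other 7 leader peptides, *trpL* and *thrL* among them, had none within this limit. Neither comparison was matched by number of genes. The smallest leader peptide operon had 2 genes, while 710 named operons had 1. A second hypothesis was that longer operons are read in the direction of replication more often. They were, in 94 of 130 operons with 5 or more genes (72.3%) against 342 of 710 with 1 gene (48.2%, Fisher exact p = 3.26e-07), while over all named operons the share was 51.6% (exact binomial p = 0.263). All 7 ribosomal RNA operons were read with replication. Of 10 gene lists none passed after adjustment, the closest being heat shock (9 of 10 operons) and ribosomal proteins (14 of 18), both with an adjusted exact p of 0.156. The last was that genes near the replication origin are named more often. With the genes split into 4 equal classes by distance, 67.1% of the nearest and 59.6% of the farthest were named, with 60.6% and 65.8% between them, so the share did not fall steadily. The difference of 7.43 percentage points had a rotation p of 0.0458, unadjusted.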
